A study of Homo sapiens with 12 samples.

How the data were processed

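Poly(A) RNA of 12 libraries of the H9 line was sequenced with a directional kit, in 4 groups (primed, coculture, converted, cR) of 3 libraries that the labels call biological replicates. The authors' table, as deposited, holds raw counts for 61860 human Ensembl genes, 17076 of them without a symbol, and no mouse genes. Per the labels, the authors' processing used Trimmomatic, STAR and featureCounts, with the builds GRCh38 and GRCm38 and no versions or roles given. How mouse reads were set apart, the annotation release, the strand setting and the handling of reads that match several genes are not stated. Coordinates are those of the deposited table on GRCh38, counted from 1.

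Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and drawn in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9. Genes were kept by edgeR's filterByExpr, which left 20908, and libraries were scaled by TMM factors. CPM is a gene's count divided by its library's TMM-scaled total and multiplied to a common total, and the log2 CPM used for principal components and camera had a prior count of 2. A single edgeR quasi-likelihood fit with robust dispersions on all 12 libraries and no block gave 5 contrasts, each with a two-sided test and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Genes "rose" or "fell" only where that threshold was passed. The p-values measure the spread between these libraries, and nothing states that replicates came from separate cultures. An exact permutation test of 3 libraries against 3 gives no p under 0.1, and 3 against 3 do not overlap by chance for 10% of unchanged genes.

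All 538 symbols of 32 gene lists matched the table, and a list was tested if at least 5 members passed the filter. Camera with a preset correlation of 0.01 compared each list with the other genes, with adjustment over the lists of a comparison, and was repeated with a correlation estimated per list. Fry, which tests whether a list's genes move on balance one way and compares them with no other genes, was an alternative. The lists were core, naive and primed pluripotency, eight-cell-like, trophectoderm and trophoblast, amnion, hypoblast, primitive streak and mesoderm, neuroectoderm, germ cell, fibroblast, mouse ESC genes, DNA methylation enzymes, imprinted genes, targets of FGF/ERK, NODAL/TGF-beta, WNT, YAP/TEAD, JAK/STAT3, p53, NF-kB and hypoxia, interferon response, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, cholesterol biosynthesis, amino acid stress, proliferation, epithelial adhesion, mesenchymal and matrix, and apoptosis regulators. Named genes followed a rule. It took a panel of 19 markers in every comparison against primed, and up to 4 members per list with the largest change at an adjusted p under 0.05, at least 2-fold, with a mean of at least 1 CPM in the higher group and no overlap. It also took the 6 largest rises and 6 largest falls with a symbol, without overlap and with at least 10 CPM, passing over pseudogenes and clone names. Groups, comparisons, lists, the naming rule and the alternatives, apart from the GC correction, were fixed before the data were examined.

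The similarity of changes against primed was set beside 20 simulations of unchanged groups that share the primed libraries. Alternatives were RLE size factors, total-count scaling, no low-count filter, a filter of CPM above 1 in at least 3 libraries, a replicate block, only the 6 libraries compared, each library left out in turn, DESeq2, an estimated correlation or fry for the lists, and genes of at least 10 CPM for the similarities. Removing each library's trend on GC content was added after seeing the data. Replicate numbers were checked for pairing, and residuals of the same number correlated between -0.0140 and 0.0222, never above 0.1, so no pairing was used. The method was tested on simulated data with 50 genes changed 1.5-, 2-, 4- and 8-fold each: it recovered 30, 37, 49 and 47 in coculture against primed, 38, 37, 50 and 49 in converted against primed, 22, 34, 43 and 47 in cR against primed, 27, 36, 46 and 48 in converted against cR and 33, 32, 47 and 47 in converted against coculture. False calls there were 13 of 19986, 17 of 19981, 9 of 19952, 8 of 19996 and 6 of 19974 genes. Camera called the raised list in each comparison and 0 of 50 unchanged lists. That does not test its preset correlation on real lists, where an estimated one ended calls. The share of counts on mouse genes was left out because the table holds none.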

Results

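Poly(A) RNA was sequenced from H9 (WA09), an established human embryonic stem cell (ESC) line, in 4 groups of 3 libraries. Primed libraries came from conventional human ESCs, and coculture libraries from human ESCs grown together with mouse ESCs. Converted libraries came from cells of the coculture route that the series title calls naive-like, and cR libraries from chemically reset naive cells. Naive and primed are an earlier and a later state of pluripotency. Total counts over human genes in replicates 1, 2 and 3 were 16181937, 15548005 and 15290612 in primed, 12880392, 17218829 and 15270528 in coculture, 11921201, 13098138 and 12488841 in converted and 13245531, 11347097 and 12021362 in cR. At this depth 3 counts summed over a group stand for 0.0590 CPM (library-scaled counts, below) in primed, 0.0660 in coculture, 0.0837 in converted and 0.0855 in cR, and these floors cover counting error only. Levels below are mean CPM ± SD with n = 3 libraries per group. A group whose libraries were all at 0 is given as 0, and a fold against it is a lower bound computed at the floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio of counts is given with its exact 95% counting interval.

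The libraries fell into 3 clusters: primed, coculture, and converted together with cR. The first principal component of the 500 most variable genes held 91.4% of the variance and the second 7.66%. Mean distances between libraries were 149 from primed to converted, 149 from primed to cR and 62.0 from primed to coculture. Converted and cR libraries lay 14.8 apart, against 13.3 within converted and 13.6 within cR. The biological coefficient of variation was 4.45% in primed, 13.1% in coculture, 5.40% in converted and 5.06% in cR. Coculture replicate 3 stood apart from its group: it differed at least 2-fold from the mean of the others in 118 of 11172 genes of at least 10 CPM, against 37 genes between replicates 1 and 2. Mitochondrially encoded genes took 5.64 ± 0.393% of counts in primed, 2.70 ± 0.299% in coculture, 5.54 ± 0.270% in converted and 5.17 ± 0.0434% in cR. In the same order, processed pseudogenes took 3.54 ± 0.0706%, 4.87 ± 0.0985%, 3.78 ± 0.0242% and 3.71 ± 0.0525%, and protein-coding genes 89.9 ± 0.138%, 88.2 ± 0.132%, 89.4 ± 0.122% and 89.5 ± 0.186%.

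**Figure D1:**
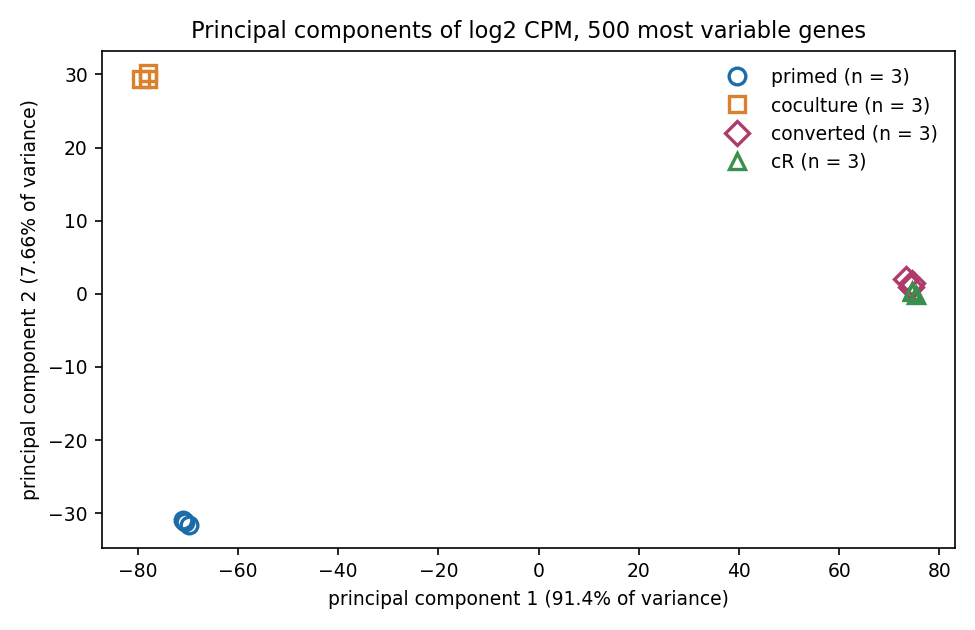
Each point is a library placed on the first 2 principal components of log2 CPM, with the share of variance on each axis and the symbol giving the group (n = 3 each). Converted and cR libraries share a place on the right, and primed and coculture libraries separate on the second axis, which holds 7.66% of the variance.

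Coculture against primed asks what differs in human ESCs while mouse ESCs are present. No group held human ESCs under the coculture conditions without mouse ESCs. Effects of the mouse cells and of other culture conditions therefore cannot be told apart. The pluripotency network was lower in coculture. POU5F1 (OCT4; ENSG00000204531, chromosome 6, 31164337 to 31180731 of GRCh38), a transcription factor that pluripotent cells need, fell 4.49-fold, from 964 ± 34.9 to 215 ± 25.7 CPM (log2 fold change -2.17 ± 0.11 (SE), edgeR adjusted p = 2.53e-18). NANOG (ENSG00000111704, chromosome 12, 7787794 to 7799146), its partner in the core network, fell 18.4-fold, from 61.1 ± 1.16 to 3.35 ± 1.08 CPM (log2 fold change -4.203 ± 0.27 (SE), edgeR adjusted p = 6.61e-22). TDGF1, a co-receptor for NODAL, fell 202-fold, from 299 ± 10.8 to 1.42 ± 0.658 CPM. L1TD1, an RNA-binding protein of pluripotent cells, fell 30.8-fold, from 561 ± 6.33 to 18.3 ± 3.43 CPM. SOX2, the third core factor, was 1.15-fold higher at 426 ± 48.1 against 369.5 ± 26.1 CPM (edgeR adjusted p = 0.0170), a call that ended with total-count scaling (adjusted p = 0.233) or without primed replicate 2 (adjusted p = 0.0725; range over the alternatives 0.000344 to 0.233).

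In the core pluripotency list, 4 of 13 rose, 8 fell and 1 did not pass (median log2 change -0.85, camera adjusted p = 0.00318). Among naive markers, of 27 measured members 1 rose, 11 fell and 15 did not pass (median log2 change -1.19, camera adjusted p = 0.0147, but adjusted p = 0.144 with an estimated correlation). ZFP42, a zinc finger gene of both states, fell 9.41-fold, from 63.6 ± 1.03 to 6.70 ± 1.56 CPM, and the naive factors TFCP2L1 and KLF4 were at 0.647 ± 0.138 against 6.10 ± 0.329 CPM and 0.570 ± 0.254 against 4.19 ± 0.395 CPM. SUSD2, a surface marker of naive cells, fell 2.44-fold, from 5.97 ± 0.451 to 2.44 ± 0.0355 CPM. DPPA3 fell from 0.313 ± 0.120 to 0.0255 ± 0.0442 CPM, a count ratio of 14.3 (95% interval 2.22 to 599). KLF17 and the trophectoderm factor GATA3 had no counts in either group, DPPA5 was at 0 against 0.0402 ± 0.0696 CPM, which did not pass, and neither did ESRRB (1.83 ± 0.304 against 1.30 ± 0.213 CPM). DNMT3L, at 0.0764 ± 0.132 against 0.198 ± 0.125 CPM, did not pass (edgeR adjusted p = 0.207); all its counts in coculture lay in replicate 2, and without that library, against 0 counts, it did (adjusted p = 0.00666; range 0.00666 to 0.580). Primed markers were lower as well: 6 of 25 rose and 19 fell (median log2 change -1.66, camera adjusted p = 0.000161). OTX2, a transcription factor of primed cells, fell 31.4-fold, from 184 ± 7.05 to 5.86 ± 2.35 CPM. SFRP2, a secreted WNT antagonist, fell 9.51-fold, from 225 ± 5.08 to 23.6 ± 3.44 CPM. The surface marker CD24 fell 2.94-fold, from 1817 ± 43.1 to 618 ± 19.04 CPM. GRHL2, an epithelial transcription factor, fell from 30.4 ± 0.966 to 0.140 ± 0.155 CPM. ZIC2, a zinc finger transcription factor, fell 1.30-fold, from 313 ± 13.4 to 240.1 ± 7.70 CPM.

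Transcripts of FGF and ERK signalling were lower in coculture: of 21 measured members 4 rose, 15 fell and 2 did not pass (median log2 change -1.91, camera adjusted p = 9.15e-05). DUSP6, a phosphatase that acts on ERK, fell from 79.8 ± 1.26 to 0.166 ± 0.108 CPM. SPRY4, a feedback inhibitor of receptor signalling, fell from 80.3 ± 2.24 to 0.115 ± 0.138 CPM. ETV5, a transcription factor induced by FGF, fell at least 396-fold, from 26.1 ± 1.61 to 0 CPM. WNT targets were higher: 10 of 14 measured rose, 2 fell and 2 did not pass (median log2 change 2.28, camera adjusted p = 3.83e-05). SP5, a direct WNT target, rose from 0.0383 ± 0.0663 to 86.9 ± 9.87 CPM, a count ratio of 2195 (95% interval 607 to 18132). LEF1, a partner of beta-catenin, rose 22.6-fold, from 1.16 ± 0.242 to 26.3 ± 5.86 CPM. NODAL and TGF-beta targets moved both ways: 5 of 15 rose, 7 fell and 3 did not pass (camera adjusted p = 0.906). GDF3 fell from 1.49 ± 0.101 to 0.0510 ± 0.0884 CPM, a count ratio of 33.9 (95% interval 9.08 to 285). In the YAP/TEAD list, of 15 measured members 9 rose, 5 fell and 1 did not pass (camera adjusted p = 0.435), with FJX1 at 22.3 ± 6.15 against 6.86 ± 0.273 CPM and F3 at 0.653 ± 0.437 against 4.02 ± 0.782 CPM.

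All 15 measured hypoxia targets rose (median log2 change 2.77, camera adjusted p = 7.57e-11), as did glycolysis, where of 20 measured members 18 rose, 1 fell and 1 did not pass (median log2 change 2.01, camera adjusted p = 1.51e-13). NDRG1, induced by low oxygen, rose 139-fold, from 2.28 ± 0.0961 to 319 ± 16.9 CPM. PFKFB4, which makes the activator of phosphofructokinase, rose 43.4-fold, from 11.2 ± 0.480 to 485 ± 13.9 CPM. SLC16A3, a lactate exporter, rose 60.1-fold, from 5.13 ± 1.39 to 308 ± 58.2 CPM. SLC2A1, the glucose transporter GLUT1, rose 8.16-fold, from 183 ± 8.19 to 1489 ± 60.8 CPM. PGK1, a glycolytic kinase, rose 7.23-fold, from 289 ± 1.81 to 2086 ± 62.3 CPM. Mitochondrially encoded mRNAs, which took 5.64% of counts in primed and 2.70% in coculture, were lower, where of 13 measured members 12 fell and 1 did not pass (median log2 change -0.99, camera adjusted p = 2.11e-06, but adjusted p = 0.127 with an estimated correlation). MT-ATP6 fell 4.43-fold, from 4283 ± 453 to 966 ± 126 CPM. MT-CO2 fell 3.86-fold, from 3493 ± 341 to 906 ± 99.8 CPM. Nuclear-encoded oxidative phosphorylation genes moved both ways: 9 of 28 rose, 9 fell and 10 did not pass (camera adjusted p = 0.905). Cholesterol synthesis genes were higher, and of 20 measured members 18 rose and 2 did not pass (median log2 change 1.57, camera adjusted p = 7.57e-11, but adjusted p = 0.0765 with an estimated correlation). INSIG1, a sterol sensor, rose 6.82-fold, from 36.7 ± 1.49 to 251 ± 56.9 CPM. The enzyme HMGCS1 rose 5.11-fold, from 308 ± 7.32 to 1572 ± 479.8 CPM. In the amino acid stress list, 4 of 17 rose, 5 fell and 8 did not pass (camera adjusted p = 0.905). DDIT4, an inhibitor of mTOR signalling, rose 28.02-fold, from 51.5 ± 2.38 to 1445 ± 97.8 CPM. CHAC1 fell 5.95-fold, from 27.0 ± 2.75 to 4.58 ± 1.52 CPM.

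Proliferation genes were lower, and of 20 measured members 1 rose and 19 fell (median log2 change -0.92, camera adjusted p = 1.49e-09, but adjusted p = 0.0758 with an estimated correlation). CCNE1 fell 3.13-fold, from 34.1 ± 2.97 to 10.9 ± 1.74 CPM. E2F1 fell 3.13-fold, from 40.0 ± 2.29 to 12.8 ± 1.23 CPM. Among p53 targets, 16 of 22 rose, 4 fell and 2 did not pass (median log2 change 1.38, camera adjusted p = 2.25e-07). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 35.4-fold, from 5.32 ± 0.534 to 189 ± 5.32 CPM. The stress cytokine GDF15 rose 25.9-fold, from 2.03 ± 0.236 to 52.6 ± 11.9 CPM. Epithelial adhesion genes were lower: 1 of 16 rose and 15 fell (median log2 change -1.19, camera adjusted p = 2.09e-07). ESRP1, an epithelial splicing factor, fell 81.7-fold, from 170.0 ± 6.62 to 2.10 ± 0.508 CPM. CDH1 (E-cadherin) fell 7.71-fold, from 360.5 ± 12.8 to 46.7 ± 2.85 CPM. Mesenchymal and matrix genes were higher, and of 15 measured members 10 rose, 3 fell and 2 did not pass (median log2 change 0.59, camera adjusted p = 0.0198, but adjusted p = 0.0640 with an estimated correlation). VIM (vimentin) rose 18.05-fold, from 132 ± 3.51 to 2386 ± 123 CPM. ZEB2, a repressor of CDH1, rose 99.1-fold, from 1.57 ± 0.371 to 157 ± 6.01 CPM. The fibroblast list was higher too, and of 11 measured members 9 rose, 1 fell and 1 did not pass (median log2 change 1.55, camera adjusted p = 0.000330). COL1A2 rose 4.18-fold, from 133 ± 3.65 to 556 ± 16.3 CPM. TAGLN rose 4.32-fold, from 35.3 ± 1.196 to 153 ± 40.3 CPM.

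Neuroectoderm markers were higher in coculture: 9 of 11 measured rose and 2 fell (median log2 change 2.20, camera adjusted p = 0.00111). DLK1, an imprinted gene of the NOTCH ligand family, rose 216-fold, from 3.86 ± 0.321 to 834 ± 92.8 CPM, and the neural transcription factors SOX1 and POU3F2 also passed: SOX1 rose 84.3-fold, from 0.216 ± 0.0305 to 19.01 ± 2.65 CPM. POU3F2 rose from 0.0772 ± 0.0875 to 17.02 ± 5.59 CPM. Imprinted genes were higher: 17 of 21 measured rose, 3 fell and 1 did not pass (median log2 change 1.22, camera adjusted p = 8.86e-06). The long noncoding RNA MEG3 rose 15.6-fold, from 0.733 ± 0.420 to 11.4 ± 0.267 CPM. CDKN1C, a cell cycle inhibitor, rose 10.9-fold, from 15.4 ± 2.13 to 169 ± 20.9 CPM. Hypoblast markers were higher, where of 11 measured members 6 rose, 1 fell and 4 did not pass (median log2 change 0.83, camera adjusted p = 0.0198, but adjusted p = 0.0695 with an estimated correlation). CER1 rose from 0.252 ± 0.237 to 2.72 ± 0.570 CPM. GATA4 rose at least 15.7-fold, from 0 to 0.934 ± 0.539 CPM. DNA methylation enzymes were lower: 1 of 12 rose, 9 fell and 2 did not pass (median log2 change -0.68, camera adjusted p = 0.00410). The de novo methyltransferase DNMT3B fell 5.30-fold, from 1216 ± 15.4 to 229 ± 6.71 CPM. TET1, which oxidises methylcytosine, rose 2.55-fold, from 105 ± 4.87 to 267 ± 9.92 CPM. Orthologues of mouse ESC genes were not called as a list (of 11 measured members 4 rose, 3 fell and 4 did not pass, camera adjusted p = 0.277). KLF2 rose at least 45.1-fold, from 0 to 2.71 ± 1.58 CPM. NR5A2 fell 3.34-fold, from 1.71 ± 0.349 to 0.510 ± 0.0447 CPM.

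The other lists were not called. Among trophectoderm markers, 2 of 9 measured rose, 2 fell and 5 did not pass (camera adjusted p = 0.906). NR2F2 rose at least 176-fold, from 0 to 10.5 ± 1.85 CPM. Among amnion markers, 1 of 7 measured rose, 4 fell and 2 did not pass (camera adjusted p = 0.4496). IGFBP5 rose 107-fold, from 12.6 ± 1.47 to 1349 ± 168 CPM. IGFBP3 fell from 9.37 ± 1.40 to 0.252 ± 0.236 CPM. For primitive streak and mesoderm, 2 of 7 measured rose, 2 fell and 3 did not pass (camera adjusted p = 0.761). The receptor KDR fell 39.8-fold, from 34.5 ± 2.13 to 0.851 ± 0.494 CPM. MIXL1 rose 4.59-fold, from 0.564 ± 0.340 to 2.66 ± 0.643 CPM, while the fall of LHX1 (0.430 ± 0.126 against 1.31 ± 0.719 CPM) ended without primed replicate 1 (adjusted p = 0.170) and in DESeq2 (adjusted p = 0.0740; range 0.00728 to 0.170). Eight-cell-like genes were near 0: of 20 measured members 1 rose, 2 fell and 17 did not pass (camera adjusted p = 0.905), with SLC34A2 at 1.01 ± 0.524 against 3.32 ± 0.239 CPM and KLF5 at 0.950 ± 0.333 against 2.13 ± 0.440 CPM. In the germ cell list, 3 of 9 measured rose, 1 fell and 5 did not pass (camera adjusted p = 0.277). TFAP2C rose 4.24-fold, from 8.44 ± 0.821 to 35.7 ± 4.80 CPM. PRDM1 rose from 0.193 ± 0.238 to 1.33 ± 0.562 CPM. For JAK/STAT3, 5 of 14 rose, 5 fell and 4 did not pass (camera adjusted p = 0.435). For NF-kB, of 9 measured members 3 rose, 2 fell and 4 did not pass (camera adjusted p = 0.669), with ICAM1 at 10.2 ± 1.83 against 3.22 ± 0.248 CPM. Interferon genes split: 6 of 12 measured rose, 3 fell and 3 did not pass (camera adjusted p = 0.277). IFITM3 rose 2.85-fold, from 85.0 ± 2.66 to 242 ± 7.29 CPM.

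In the apoptosis list, 3 of 17 rose, 10 fell and 4 did not pass (median log2 change -0.76, camera adjusted p = 0.0717). PMAIP1, a BH3-only protein, fell 14.8-fold, from 146 ± 6.57 to 9.88 ± 1.01 CPM. Camera called this list lower without a filter (adjusted p = 0.0122) and without coculture replicate 3 (adjusted p = 0.0248; range over the alternatives 1.28e-07 to 0.134). The largest falls by the naming rule included FOXD3 (fell at least 219-fold, from 14.4 ± 0.482 to 0 CPM), a transcription factor, and the metallothionein MT1G (fell at least 216-fold, from 14.3 ± 1.34 to 0 CPM). Among the largest rises were HOTAIRM1, a noncoding RNA of the HOXA cluster (rose at least 172-fold, from 0 to 10.02 ± 3.26 CPM) and the homeobox gene NKX6-1 (rose from 0.135 ± 0.144 to 52.3 ± 19.4 CPM).

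By edgeR, 13291 of 20908 genes changed, 6364 higher and 6927 lower, and 5657 did so at least 2-fold (2604 higher, 3053 lower). The split was 5408 higher and 7945 lower with total-count scaling. Adjusted p-values of the 122 named genes that passed in edgeR were 5.56e-28 to 0.0170, with no overlap between groups. Their log2 SE were 0.03 to 0.69 where both groups had over 3 counts. Camera called 18 of 32 lists, and 12 with an estimated correlation. Adjusted over the list alone, the gene counts were the same in 30 lists, and differed in germ cell (3 rose, 0 fell) and DNA methylation enzymes (2 rose, 9 fell). Median, mean and test differed in sign in 5 uncalled lists: trophectoderm and trophoblast, NODAL/TGF-beta, NF-kB, interferon response and amino acid stress. Replicate 3 of coculture differed from replicates 1 and 2 by a median log2 of -0.52 in NODAL/TGF-beta targets, 0.38 in cholesterol biosynthesis, 0.30 in YAP/TEAD targets, -0.29 in core pluripotency, -0.26 in amino acid stress, 0.25 in imprinted genes and 0.24 in mitochondrially encoded genes, and by under 0.2 either way in the other lists. Without it, 13368 genes changed, 5582 of them at least 2-fold. The table holds no mouse genes, so the amount of mouse RNA in the coculture libraries could not be measured.

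**Figure D2:**
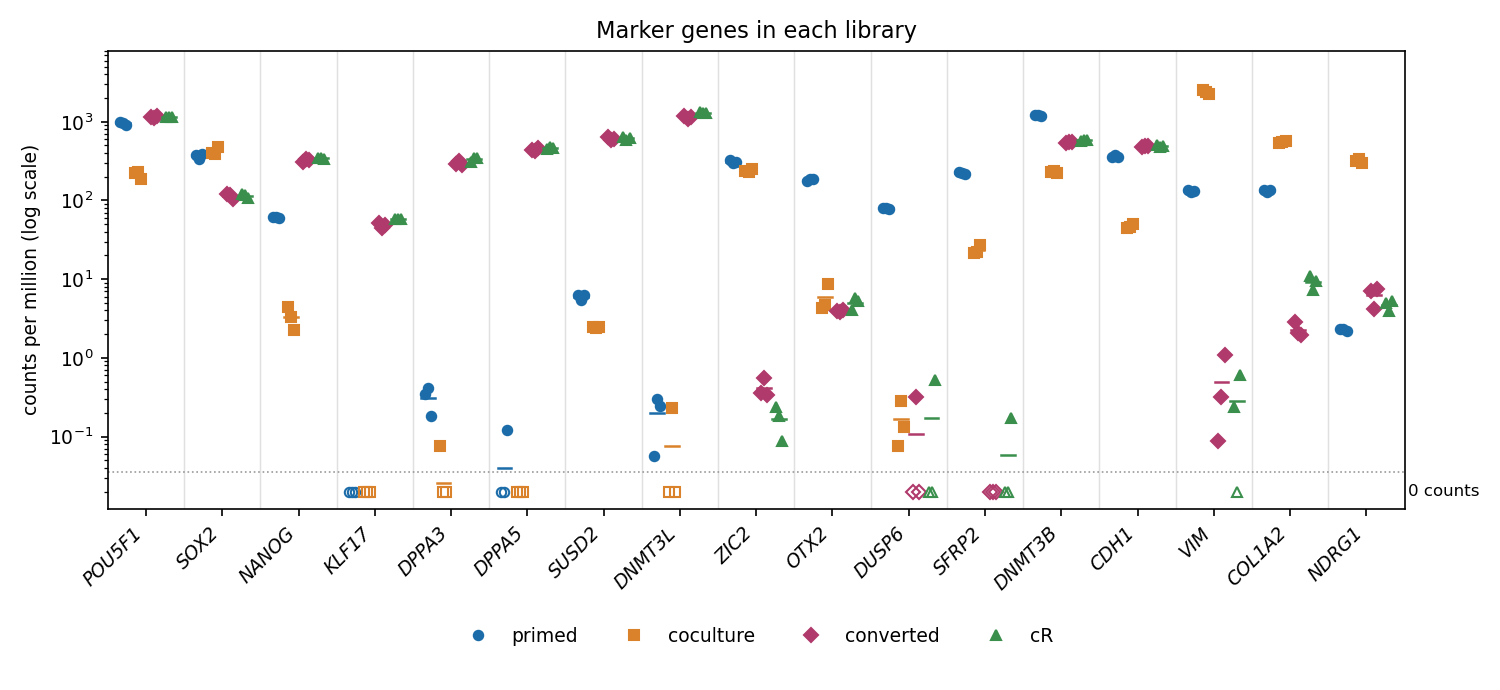
CPM on a log axis for named genes, with a point per library, a bar at the mean of the 3 libraries of a group, and open symbols below the dotted line for libraries with 0 counts. NANOG is at 61.1 CPM in primed, 3.35 in coculture, 324 in converted and 342 in cR, and VIM is highest in coculture.

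Converted against primed asks what differs once cells of the coculture route are in the naive-like state. All 27 measured naive markers rose and 24 of 25 measured primed markers fell. KLF17 (ENSG00000171872, chromosome 1, 44118821 to 44135140), a transcription factor of naive cells, rose at least 822-fold, from 0 to 48.6 ± 3.58 CPM. DPPA3, a germ cell and early embryo protein, rose 912-fold, from 0.313 ± 0.120 to 295 ± 18.7 CPM (log2 fold change 9.83 ± 0.24 (SE), edgeR adjusted p = 3.56e-28). SUSD2 rose 102-fold, from 5.97 ± 0.451 to 611 ± 27.0 CPM. TFCP2L1 rose 33.997-fold, from 6.10 ± 0.329 to 207 ± 6.47 CPM. KLF4 rose 37.8-fold, from 4.19 ± 0.395 to 159 ± 10.4 CPM. DPPA5 rose from 0.0402 ± 0.0696 to 441 ± 20.8 CPM, a count ratio of 11212 (95% interval 3103 to 92592). The primed factor ZIC2 (ENSG00000043355, chromosome 13, 99981784 to 99986765) fell 732-fold, from 313 ± 13.4 to 0.415 ± 0.124 CPM. OTX2 fell 46.7-fold, from 184 ± 7.05 to 3.93 ± 0.101 CPM.

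For the naive list (median log2 change 9.66, or 9.11 with zero genes at their bound), the camera adjusted p was 1.16e-16. NLRP7, a maternal-effect gene, rose at least 85583-fold, from 0 to 5049.5 ± 111.99 CPM. The zinc finger gene ZNF729 rose at least 9159-fold, from 0 to 539 ± 48.5 CPM. OLAH, a fatty acid thioesterase, rose at least 2349-fold, from 0 to 138 ± 4.22 CPM. For the primed list, 1 of 25 rose and 24 fell (median log2 change -5.55, camera adjusted p = 4.51e-12). PTPRZ1, a receptor phosphatase, fell at least 4414-fold, from 369 ± 6.42 to 0 CPM. SFRP2 fell at least 2687-fold, from 225 ± 5.08 to 0 CPM. The surface marker THY1 (CD90) fell at least 1801-fold, from 151 ± 8.15 to 0 CPM. CD24 fell 38.8-fold, from 1817 ± 43.1 to 46.9 ± 1.09 CPM. All 20 measured eight-cell-like genes rose (median log2 change 6.82, 5.74 with zero genes at their bound, camera adjusted p = 6.79e-08), to levels below 10 CPM in TRIM43B (rose at least 141-fold, from 0 to 8.33 ± 0.719 CPM) and TRIM49 (rose at least 131-fold, from 0 to 7.72 ± 1.33 CPM). Of the core factors, NANOG rose 5.30-fold, from 61.1 ± 1.16 to 324 ± 10.3 CPM. GDF3 rose 113-fold, from 1.49 ± 0.101 to 169 ± 4.64 CPM. SOX2 fell 3.24-fold, from 369.5 ± 26.1 to 114 ± 8.24 CPM. POU5F1 rose 1.203-fold, from 964 ± 34.9 to 1159.6 ± 45.5 CPM (edgeR adjusted p = 0.000365), a call that ended with total-count scaling (adjusted p = 0.264; range 2.22e-10 to 0.264). Total-count scaling shifted the median log2 change of all genes to -0.12 in coculture, -0.20 in converted and -0.20 in cR against primed, and changes are relative to that shift.

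FGF and ERK targets were lower, and of 21 measured members 1 rose, 18 fell and 2 did not pass (median log2 change -3.10, camera adjusted p = 2.86e-06). SPRY4 fell at least 960.1-fold, from 80.3 ± 2.24 to 0 CPM. DUSP6 fell from 79.8 ± 1.26 to 0.106 ± 0.184 CPM. YAP/TEAD targets were lower, and of 15 measured members 2 rose, 11 fell and 2 did not pass (median log2 change -1.41, camera adjusted p = 0.0115, but adjusted p = 0.187 with an estimated correlation). The receptor AXL fell 176-fold, from 45.8 ± 2.07 to 0.253 ± 0.0934 CPM. The coagulation receptor F3 rose 24.3-fold, from 4.02 ± 0.782 to 97.6 ± 6.86 CPM. Oxidative phosphorylation genes were higher: 26 of 28 rose and 2 did not pass (median log2 change 1.15, camera adjusted p = 2.71e-09). NDUFV1, a subunit of complex I, rose 6.02-fold, from 75.0 ± 5.41 to 451 ± 22.6 CPM. Germ cell genes were higher: 8 of 9 measured rose and 1 fell (median log2 change 4.01, camera adjusted p = 0.00735). MAEL rose at least 277-fold, from 0 to 16.3 ± 1.502 CPM. For p53 targets, 15 of 22 rose, 6 fell and 1 did not pass (median log2 change 1.24, camera adjusted p = 0.0115). GDF15 rose 25.9-fold, from 2.03 ± 0.236 to 52.7 ± 6.66 CPM. Fibroblast genes were lower: 1 of 11 measured rose, 8 fell and 2 did not pass (median log2 change -3.20, camera adjusted p = 0.00735). COL1A2 fell 58.6-fold, from 133 ± 3.65 to 2.27 ± 0.481 CPM. COL1A1 fell 35.5-fold, from 188 ± 4.84 to 5.28 ± 0.533 CPM.

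Camera called none of the other lists. Signalling and regulator lists among them were core pluripotency (7 rose and 6 fell of 13, adjusted p = 0.918), DNA methylation enzymes (7 rose and 5 fell of 12, adjusted p = 0.622) and imprinted genes (7 rose and 8 fell of 21, adjusted p = 0.999). Camera also left uncalled NODAL/TGF-beta targets (11 rose and 4 fell of 15, adjusted p = 0.112), WNT targets (9 rose and 4 fell of 14, adjusted p = 0.527) and JAK/STAT3 targets (9 rose and 3 fell of 14, adjusted p = 0.112). Camera did not call NF-kB targets (6 rose and 1 fell of 9, adjusted p = 0.0704) and interferon response (7 rose and 5 fell of 12, adjusted p = 0.515). DNMT3L (ENSG00000142182, chromosome 21, 44246339 to 44262216), a cofactor of the de novo methyltransferases, rose 5586-fold, from 0.198 ± 0.125 to 1148 ± 48.97 CPM. ZFP57, which protects imprints, rose 295-fold, from 0.215 ± 0.0854 to 66.4 ± 4.79 CPM. DNMT3B fell 2.22-fold, from 1216 ± 15.4 to 549 ± 7.25 CPM. The imprinted noncoding RNA MEG3 rose 1970.5-fold, from 0.733 ± 0.420 to 1451 ± 86.3 CPM. H19 rose 27.3-fold, from 4.40 ± 0.337 to 120.2 ± 12.3 CPM. NODAL, a TGF-beta family ligand, rose 102-fold, from 1.90 ± 0.301 to 195 ± 6.34 CPM. The WNT receptor FZD7 fell 716-fold, from 306 ± 0.362 to 0.422 ± 0.314 CPM. IL6ST, the shared cytokine receptor gp130, rose 20.7-fold, from 10.8 ± 0.558 to 223 ± 5.61 CPM. BST2, an interferon-induced restriction factor, fell 38.9-fold, from 99.1 ± 3.82 to 2.53 ± 0.229 CPM.

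Uncalled metabolic and cell state lists in camera were glycolysis (13 rose and 6 fell of 20, adjusted p = 0.112), hypoxia targets (7 rose and 2 fell of 15, adjusted p = 0.190) and amino acid stress response (10 rose and 4 fell of 17, adjusted p = 0.112). Also uncalled by camera were cholesterol biosynthesis (11 rose and 5 fell of 20, adjusted p = 0.318), mitochondrially encoded (4 rose and 0 fell of 13, adjusted p = 0.459) and proliferation (6 rose and 10 fell of 20, adjusted p = 0.670). Nor did camera call epithelial adhesion (7 rose and 9 fell of 16, adjusted p = 0.624), mesenchymal and matrix (5 rose and 9 fell of 15, adjusted p = 0.478) and apoptosis regulators (9 rose and 8 fell of 17, adjusted p = 0.651). PFKM, a phosphofructokinase, fell 8.14-fold, from 125 ± 3.86 to 15.4 ± 1.17 CPM. BNIP3, a mitophagy receptor, was at 194 ± 20.1 against 41.8 ± 3.74 CPM. TRIB3, a stress-induced pseudokinase, rose 7.89-fold, from 12.5 ± 2.13 to 98.9 ± 2.47 CPM. CCNE1, a cyclin, rose 2.36-fold, from 34.1 ± 2.97 to 80.7 ± 2.17 CPM. CLDN3, a tight junction claudin, fell 15.9-fold, from 11.7 ± 0.873 to 0.730 ± 0.228 CPM. CDH2 (N-cadherin) fell 75.6-fold, from 76.5 ± 2.76 to 1.004 ± 0.0736 CPM. VIM fell from 132 ± 3.51 to 0.498 ± 0.523 CPM. CASP8, an initiator caspase, rose 18.9-fold, from 2.57 ± 0.135 to 48.8 ± 3.49 CPM.

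Lineage lists that camera did not call were trophectoderm and trophoblast (4 rose and 4 fell of 9, adjusted p = 0.999), amnion (3 rose and 4 fell of 7, adjusted p = 0.705) and hypoblast (5 rose and 5 fell of 11, adjusted p = 0.716). Camera also left uncalled primitive streak and mesoderm (3 rose and 3 fell of 7, adjusted p = 0.992), neuroectoderm (3 rose and 7 fell of 11, adjusted p = 0.140) and mouse ESC genes (7 rose and 2 fell of 11, adjusted p = 0.203). GATA3 rose at least 29.3-fold, from 0 to 1.73 ± 0.252 CPM. HNF4A, of hypoblast and endoderm, rose at least 232-fold, from 0 to 13.7 ± 0.430 CPM. GATA4 rose at least 24.6-fold, from 0 to 1.44 ± 0.424 CPM. MIXL1, of the primitive streak, rose 18.1-fold, from 0.564 ± 0.340 to 10.5 ± 1.09 CPM. MAP2, a neuronal microtubule protein, fell at least 570.2-fold, from 47.7 ± 2.86 to 0 CPM. IGFBP5 was at 0.415 ± 0.131 against 12.6 ± 1.47 CPM. ESRRB fell from 1.30 ± 0.213 to 0.0881 ± 0.153 CPM, a count ratio of 15.5 (95% interval 5.08 to 77.1). The largest rises by the naming rule also held the zinc finger gene ZNF208 (rose at least 7183-fold, from 0 to 423 ± 28.3 CPM), and the largest falls COL4A6, a basement membrane collagen (fell at least 1311-fold, from 109.7 ± 3.67 to 0 CPM).

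In edgeR's test 15701 genes changed in converted, 7779 higher and 7922 lower, and 9009 at least 2-fold (3970 higher, 5039 lower). The split was 6521 higher and 9182 lower with total-count scaling, and 6951 higher and 8773 lower with the GC trend removed. Adjusted p-values of the 134 named genes that passed in edgeR were 2.52e-31 to 0.000811, with no overlap between groups. Their log2 SE were 0.02 to 0.70 where both groups had over 3 counts. Camera called 9 of 32 lists, and 8 with an estimated correlation. Adjusted over the list alone, the counts differed in 3 lists: YAP/TEAD (3 rose, 11 fell), glycolysis (14 rose, 6 fell) and mitochondrially encoded (3 rose, 0 fell). Median, mean and test differed in sign in 5 uncalled lists: hypoblast, primitive streak and mesoderm, imprinted genes, WNT and apoptosis. Without a filter camera called higher also the lists NODAL/TGF-beta, JAK/STAT3, NF-kB, glycolysis, amino acid stress and hypoxia (adjusted p from 0.0174 to 0.0476), and NF-kB also with total-count scaling (adjusted p = 0.0353; range over these lists and all alternatives 4.05e-11 to 0.732). How reads shared by near-identical genes were counted is not recorded, so levels of TRIM43, TRIM43B, TRIM49, MBD3L2, ALPG, MT1G, POU5F1 and NANOG, which have close copies, are uncertain, as are those of FOXD3 and JAKMIP2-AS1, since the strand setting of the counting is not recorded.

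Comparing cR with primed asks what differs in chemically reset cells. All 27 measured naive markers rose and 24 of 25 measured primed markers fell, as many as in converted. KLF17 rose at least 985-fold, from 0 to 58.1 ± 0.665 CPM. DPPA3 rose 1039-fold, from 0.313 ± 0.120 to 336 ± 20.3 CPM (log2 fold change 10.02 ± 0.24 (SE), edgeR adjusted p = 2.34e-28). SUSD2 rose 103.3-fold, from 5.97 ± 0.451 to 618 ± 24.7 CPM. TFCP2L1 rose 38.6-fold, from 6.10 ± 0.329 to 235 ± 8.29 CPM. KLF4 rose 44.1-fold, from 4.19 ± 0.395 to 185 ± 14.1 CPM. DPPA5 rose from 0.0402 ± 0.0696 to 466 ± 7.46 CPM, a count ratio of 11837 (95% interval 3276 to 97752). ZIC2 fell 1738-fold, from 313 ± 13.4 to 0.169 ± 0.0758 CPM (log2 fold change -10.76 ± 0.22 (SE), edgeR adjusted p = 6.05e-29). CD24 fell 29.6-fold, from 1817 ± 43.1 to 61.3 ± 1.46 CPM. OTX2 fell 36.8-fold, from 184 ± 7.05 to 5.03 ± 0.863 CPM. NANOG rose 5.61-fold, from 61.1 ± 1.16 to 342 ± 5.52 CPM. SOX2 fell 3.22-fold, from 369.5 ± 26.1 to 115 ± 6.32 CPM. POU5F1 rose 1.202-fold, from 964 ± 34.9 to 1158 ± 13.8 CPM (edgeR adjusted p = 0.000391). The POU5F1 call ended with total-count scaling (adjusted p = 0.257) and with the GC trend removed (adjusted p = 0.0589; range 1.03e-10 to 0.257).

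Called lists were those of converted. The naive list had a median log2 change of 9.77, or 9.30 with zero genes at their bound (camera adjusted p = 1.02e-16). NLRP7 rose at least 84159.7-fold, from 0 to 4962 ± 49.6 CPM. DNMT3L rose 6359-fold, from 0.198 ± 0.125 to 1307 ± 16.8 CPM. The primed list had a median log2 change of -5.53 (camera adjusted p = 8.71e-12), with 1 member that rose. SFRP2 fell from 225 ± 5.08 to 0.0579 ± 0.1003 CPM, a count ratio of 3942 (95% interval 1091 to 32554). All 20 measured eight-cell-like genes rose (median log2 change 7.21, camera adjusted p = 3.95e-08, with a median of 6.01 with zero genes at their bound). For FGF/ERK, 1 of 21 measured rose, 19 fell and 1 did not pass (median log2 change -3.10, camera adjusted p = 1.68e-06). SPRY4 fell from 80.3 ± 2.24 to 0.0290 ± 0.0501 CPM, a count ratio of 2818 (95% interval 505 to 111314). DUSP6 fell from 79.8 ± 1.26 to 0.174 ± 0.301 CPM. For oxidative phosphorylation, 27 of 28 rose and 1 did not pass (median log2 change 1.11, camera adjusted p = 2.03e-09). NDUFV1 rose 5.29-fold, from 75.0 ± 5.41 to 396 ± 3.23 CPM. For germ cell genes, of 9 measured members 8 rose and 1 fell (median log2 change 3.999, camera adjusted p = 0.00730, but adjusted p = 0.0556 with an estimated correlation). MAEL rose at least 344-fold, from 0 to 20.3 ± 1.06 CPM. For YAP/TEAD, of 15 measured members 1 rose, 11 fell and 3 did not pass (median log2 change -1.43, camera adjusted p = 0.00785, but adjusted p = 0.149 with an estimated correlation). AMOTL1 fell 11.9-fold, from 65.1 ± 1.91 to 5.50 ± 0.524 CPM. For p53, of 22 measured members 15 rose and 7 fell (median log2 change 1.11, camera adjusted p = 0.0267, but adjusted p = 0.0809 with an estimated correlation; adjusted p = 0.0579 on only the 6 libraries compared, range 1.07e-10 to 0.0809). GDF15 rose 17.5-fold, from 2.03 ± 0.236 to 35.5 ± 4.08 CPM. For the fibroblast list, of 11 measured members 1 rose, 8 fell and 2 did not pass (median log2 change -3.51, camera adjusted p = 0.0235, but adjusted p = 0.0809 with an estimated correlation; adjusted p = 0.0580 on only the 6 libraries, range 1.73e-10 to 0.0809). COL1A2 fell 14.2-fold, from 133 ± 3.65 to 9.28 ± 1.88 CPM. COL3A1 rose from 0.0402 ± 0.0696 to 9.55 ± 1.52 CPM, a count ratio of 243 (95% interval 66.7 to 2015).

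By camera, uncalled signalling and regulator lists were core pluripotency (7 rose and 6 fell of 13, adjusted p = 0.760) and DNA methylation enzymes (7 rose and 5 fell of 12, adjusted p = 0.499). Camera did not call imprinted genes (8 rose and 10 fell of 21, adjusted p = 0.935) and NODAL/TGF-beta targets (10 rose and 4 fell of 15, adjusted p = 0.0974). Others that camera did not call were WNT targets (7 rose and 5 fell of 14, adjusted p = 0.696) and JAK/STAT3 targets (9 rose and 5 fell of 14, adjusted p = 0.269). Also uncalled by camera were NF-kB targets (5 rose and 2 fell of 9, adjusted p = 0.126) and interferon response (6 rose and 5 fell of 12, adjusted p = 0.548). GDF3, a TGF-beta family ligand, rose 135-fold, from 1.49 ± 0.101 to 203 ± 3.44 CPM. NODAL rose 107-fold, from 1.90 ± 0.301 to 205 ± 7.38 CPM. MEG3 rose 2216-fold, from 0.733 ± 0.420 to 1632 ± 35.9 CPM. IL6ST rose 18.3-fold, from 10.8 ± 0.558 to 197 ± 3.03 CPM. TET2, an enzyme that oxidises methylcytosine, rose 3.08-fold, from 8.89 ± 1.002 to 27.4 ± 1.59 CPM. DNMT3B fell 2.09-fold, from 1216 ± 15.4 to 581 ± 8.12 CPM.

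By camera, uncalled metabolic and cell state lists were glycolysis (11 rose and 6 fell of 20, adjusted p = 0.396) and mitochondrially encoded (2 rose and 2 fell of 13, adjusted p = 0.548). Nor did camera call cholesterol biosynthesis (10 rose and 4 fell of 20, adjusted p = 0.376) and amino acid stress response (11 rose and 4 fell of 17, adjusted p = 0.0974). Camera also left uncalled hypoxia targets (8 rose and 4 fell of 15, adjusted p = 0.548), proliferation (6 rose and 8 fell of 20, adjusted p = 0.958) and epithelial adhesion (7 rose and 8 fell of 16, adjusted p = 0.694). Camera also left uncalled mesenchymal and matrix (5 rose and 9 fell of 15, adjusted p = 0.499) and apoptosis regulators (9 rose and 8 fell of 17, adjusted p = 0.705). PFKM, a phosphofructokinase, fell 7.71-fold, from 125 ± 3.86 to 16.2 ± 1.82 CPM. CDH2 fell 102-fold, from 76.5 ± 2.76 to 0.749 ± 0.336 CPM. Lineage lists uncalled by camera were trophectoderm and trophoblast (4 rose and 3 fell of 9, adjusted p = 0.975), amnion (3 rose and 4 fell of 7, adjusted p = 0.760) and hypoblast (4 rose and 5 fell of 11, adjusted p = 0.760). Camera did not call primitive streak and mesoderm (3 rose and 4 fell of 7, adjusted p = 0.895), neuroectoderm (3 rose and 6 fell of 11, adjusted p = 0.129) and mouse ESC genes (7 rose and 3 fell of 11, adjusted p = 0.257). HNF4A rose at least 231-fold, from 0 to 13.7 ± 1.99 CPM. GATA3 rose at least 32.9-fold, from 0 to 1.92 ± 0.475 CPM. GATA4 rose at least 33.8-fold, from 0 to 2.02 ± 0.594 CPM. ESRRB fell from 1.30 ± 0.213 to 0.206 ± 0.234 CPM. MAP2 fell at least 558-fold, from 47.7 ± 2.86 to 0 CPM. The largest falls by the naming rule also held the forebrain factor FEZF1 (fell at least 951-fold, from 81.3 ± 2.46 to 0 CPM) and JAKMIP2-AS1 (fell at least 690.3-fold, from 59.1 ± 3.24 to 0 CPM), and the largest rises ZNF208 (rose at least 8394-fold, from 0 to 496 ± 36.6 CPM).

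In cR, 15759 genes changed by edgeR, 7740 higher and 8019 lower, and 9165 at least 2-fold (3953 higher, 5212 lower). The split was 6495 higher and 9247 lower with total-count scaling, and 6952 higher and 8834 lower with the GC trend removed. Adjusted p-values of the 138 named genes that passed in edgeR were 2.61e-31 to 0.000965, with no overlap between groups. Their log2 SE were 0.02 to 0.74 where both groups had over 3 counts. Camera called 9 of 32 lists, and 5 with an estimated correlation. Adjusted over the list alone, the counts differed only in cholesterol biosynthesis (9 rose, 4 fell). Median, mean and test differed in sign in 6 uncalled lists: trophectoderm and trophoblast, hypoblast, imprinted genes, WNT, proliferation and apoptosis. Without a filter camera called higher also NODAL/TGF-beta and amino acid stress (adjusted p from 0.0125 to 0.0154), and NODAL/TGF-beta also with total-count scaling (adjusted p = 0.0490; range over both lists 2.19e-07 to 0.593).

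**Figure D3:**
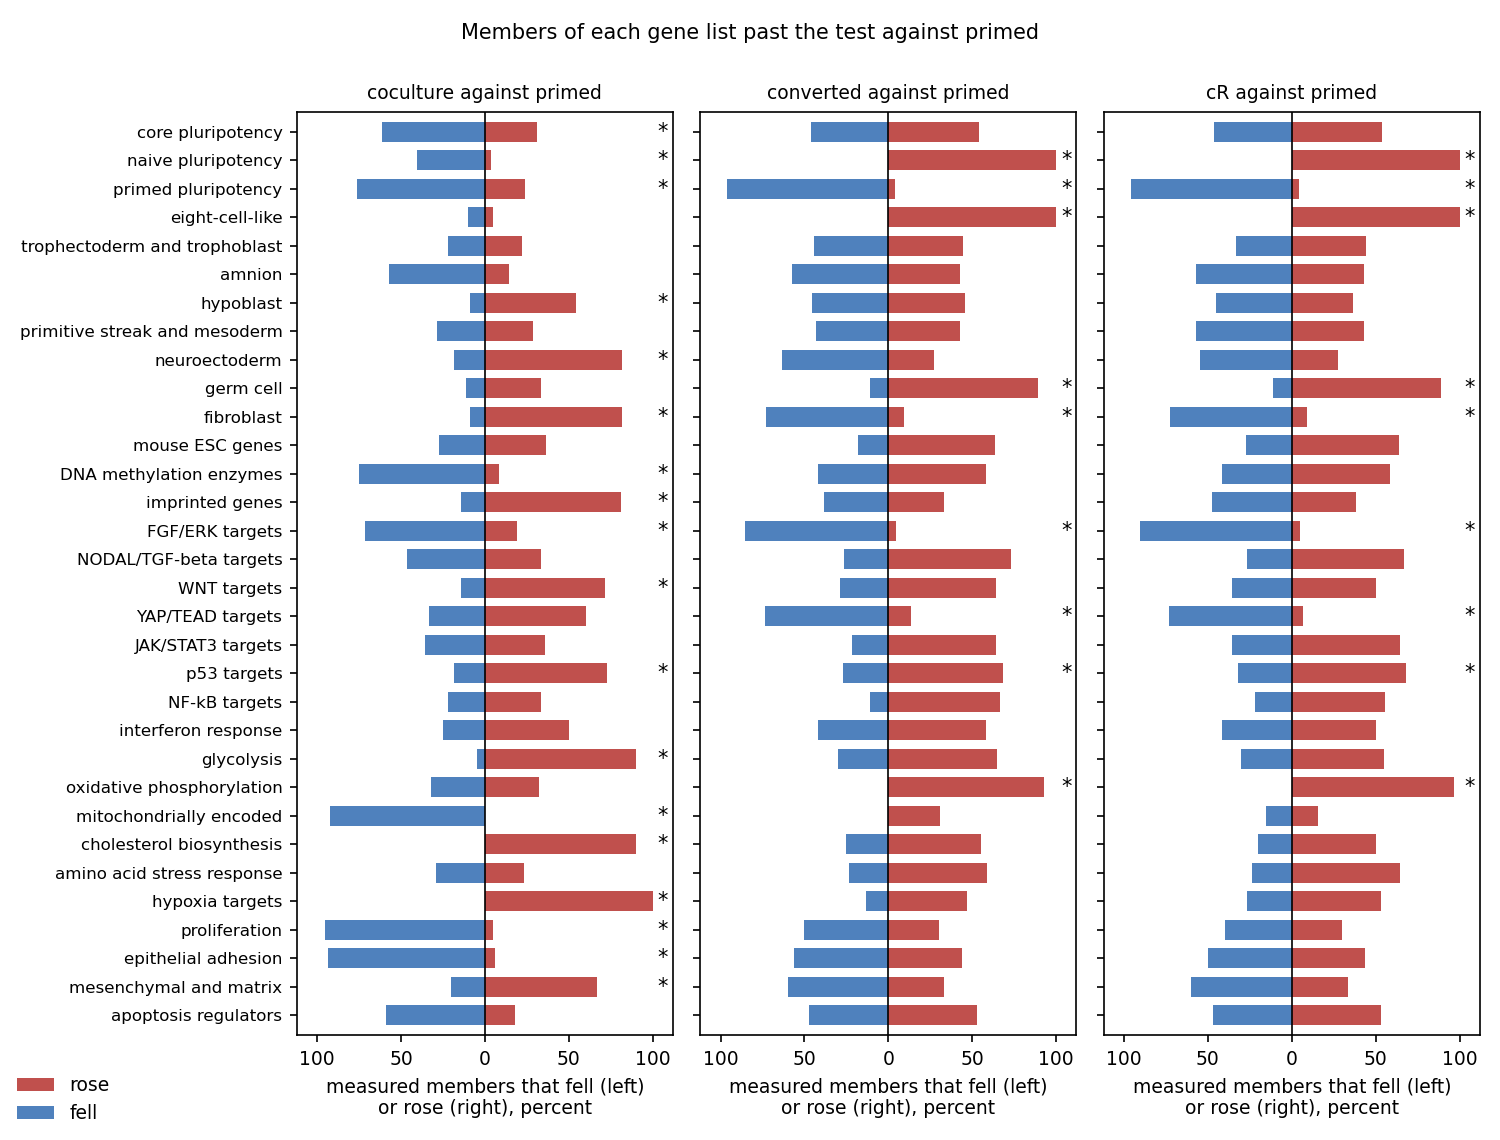
Bars give the percent of each list's measured members that rose (right of 0) or fell (left of 0) in edgeR's test at an adjusted p under 0.05, in 3 comparisons against primed, and a star marks a list that camera called. All 15 hypoxia targets rose in coculture, and all 27 naive markers rose in converted and in cR.

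The next comparison asks how far the changes of each culture against primed resemble those of cR. Of the 3953 genes at least 2-fold higher in cR, 3839 rose and 0 fell in converted, and 1219 rose, 912 fell and 1822 did not pass in coculture. The share that rose in coculture, 30.8%, was near the 30.4% of all genes tested. The share that fell was 23.1%, against 33.1% of all genes. Of the 5212 genes at least 2-fold lower in cR, 4958 fell and 0 rose in converted, and 2272 fell, 1296 rose and 1644 did not pass in coculture. Across 20908 genes, which are not independent replicates, log2 fold changes of converted and cR had a Pearson correlation of 0.975 and a Spearman correlation of 0.973, against 0.455 for unchanged groups simulated against the same primed libraries. Their covariance was 6.33 against 0.0226 simulated, a difference of 6.31. For coculture and cR the Pearson correlation was 0.199 (0.0948 for genes of at least 10 CPM and 0.283 without a filter) and Spearman's 0.143, against 0.468 simulated, and the covariance 0.748 against 0.0225, a difference of 0.726. Genes called higher in both converted and cR numbered 7201 and lower in both 7363, against 2879.7 and 3038 for independent lists, and 2 and 0 went opposite ways. For coculture and cR, 2596 were higher in both and 3386 lower in both, against 2356 and 2657, while 2132 rose in coculture and fell in cR and 2173 did the reverse. The 3 primed libraries cannot be split into groups of 2, so part of each excess of calls over independent lists or over all genes can come from the shared controls.

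Converted against cR asks how naive-like cells of the coculture route differ from chemically reset cells, and few genes did so by a large factor. The fibrillar collagens COL1A1, COL1A2 and COL3A1 were lower in converted: COL1A1 (ENSG00000108821, chromosome 17, 50184101 to 50201632) was at 5.28 ± 0.533 against 16.4 ± 2.34 CPM, 3.10-fold lower (log2 fold change -1.63 ± 0.14 (SE), edgeR adjusted p = 2.21e-09), COL1A2 at 2.27 ± 0.481 against 9.28 ± 1.88 CPM, 4.13-fold lower, and COL3A1 (ENSG00000168542, chromosome 2, 188974373 to 189012746) at 0 against 9.55 ± 1.52 CPM, at least 114-fold lower. Also lower in converted were FAM151A at 19.3 ± 2.19 against 49.5 ± 0.292 CPM (2.56-fold), ACOT11, an acyl-CoA thioesterase, at 9.80 ± 0.822 against 19.9 ± 1.46 CPM (2.03-fold), TET2 at 14.5 ± 0.389 against 27.4 ± 1.59 CPM (1.88-fold), RASSF2 at 5.69 ± 0.217 against 10.6 ± 2.32 CPM (1.86-fold) and SGCE, an imprinted gene, at 6.22 ± 1.04 against 11.5 ± 1.22 CPM (1.84-fold). Higher in converted were HSPG2 (perlecan, a basement membrane proteoglycan) at 34.04 ± 2.91 against 18.4 ± 1.02 CPM (1.85-fold, edgeR adjusted p = 1.63e-07), ACTA1 at 47.6 ± 3.73 against 26.4 ± 2.21 CPM (1.80-fold), LRRC8B, a subunit of volume-regulated anion channels, at 15.9 ± 1.17 against 8.97 ± 1.45 CPM (1.77-fold), PPFIA4 at 25.6 ± 7.34 against 13.7 ± 0.988 CPM (1.87-fold), COL23A1 at 13.4 ± 2.71 against 7.18 ± 1.66 CPM (1.86-fold) and PRAME at 19.3 ± 1.36 against 10.5 ± 2.56 CPM (1.84-fold). The calls of SGCE, COL23A1, PRAME and PPFIA4 ended when a library was left out. Without converted replicate 3, SGCE had an adjusted p of 0.0519 (range 3.58e-07 to 0.0519) and COL23A1 0.0993, and without cR replicate 3 COL23A1 had 0.0810 (range 6.72e-05 to 0.0993) and PRAME 0.0786 (range 6.12e-06 to 0.0786). PPFIA4 had an adjusted p of 0.110 without cR replicate 1, 0.103 without cR replicate 2 and 0.104 without cR replicate 3 (range 3.44e-10 to 0.110).

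Lists called by camera moved by small amounts, and none was called with an estimated correlation. Hypoxia targets were higher in converted (of 15 measured members 5 rose and 10 did not pass; median log2 change 0.38, camera adjusted p = 1.74e-07, but adjusted p = 0.105 with an estimated correlation; adjusted over the list alone, 9 rose and 0 fell). Glycolysis was higher (of 20 measured members 5 rose and 15 did not pass; median log2 change 0.16, camera adjusted p = 1.74e-07, but adjusted p = 0.281 with an estimated correlation; adjusted over the list alone, 13 rose and 1 fell). The p53 list was higher (of 22 measured members 6 rose and 16 did not pass; median log2 change 0.14, camera adjusted p = 0.000263, but adjusted p = 0.0533 with an estimated correlation; adjusted over the list alone, 8 rose and 0 fell). JAK/STAT3 targets were higher (of 14 measured members 1 rose and 13 did not pass; median log2 change 0.25, camera adjusted p = 0.00586, but adjusted p = 0.0831 with an estimated correlation; adjusted over the list alone, 6 rose and 1 fell). DNA methylation enzymes were lower (of 12 measured members 2 fell and 10 did not pass; median log2 change -0.07, camera adjusted p = 0.00415, but adjusted p = 0.0831 with an estimated correlation; adjusted over the list alone, 0 rose and 4 fell). The fibroblast list was called lower although its median was above 0 (of 11 measured members 3 fell and 8 did not pass; median log2 change 0.06, camera adjusted p = 0.0110, but adjusted p = 0.0962 with an estimated correlation; adjusted over the list alone, 0 rose and 3 fell), the 3 that fell being the collagens above, and DCN and LUM, under the expression filter, held 1 and 0 counts in converted against 12 and 17 in cR. Naive markers were not called (of 27 measured members 2 rose, 1 fell and 24 did not pass, camera adjusted p = 0.273; adjusted over the list alone, 2 rose and 11 fell), nor were primed markers (of 25 measured members 1 fell and 24 did not pass, camera adjusted p = 0.495).

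The 26 uncalled lists had camera adjusted p-values from 0.0529 to 0.982. No member changed in eight-cell-like, trophectoderm and trophoblast, amnion, germ cell, oxidative phosphorylation and mesenchymal and matrix, by either adjustment. Members changed in core pluripotency (0 rose and 3 fell of 13, 0 and 4 adjusted over the list alone), hypoblast (0 rose and 2 fell of 11), primitive streak and mesoderm (0 rose and 0 fell of 7, 1 and 1 adjusted over the list alone), neuroectoderm (1 rose and 0 fell of 11), mouse ESC genes (0 rose and 1 fell of 11) and imprinted genes (0 rose and 1 fell of 21, 0 and 2 adjusted over the list alone). Others with members that changed were FGF/ERK targets (0 rose and 1 fell of 21, 2 and 1 adjusted over the list alone), NODAL/TGF-beta targets (0 rose and 3 fell of 15), WNT targets (1 rose and 0 fell of 14), YAP/TEAD targets (2 rose and 0 fell of 15, 3 and 0 adjusted over the list alone) and NF-kB targets (0 rose and 0 fell of 9, 1 and 0 adjusted over the list alone). The last were interferon response (0 rose and 1 fell of 12), mitochondrially encoded (1 rose and 0 fell of 13), cholesterol biosynthesis (0 rose and 1 fell of 20, 0 and 2 adjusted over the list alone), amino acid stress response (2 rose and 0 fell of 17, 3 and 3 adjusted over the list alone), epithelial adhesion (1 rose and 1 fell of 16, 2 and 1 adjusted over the list alone) and apoptosis regulators (3 rose and 0 fell of 17). The proliferation list (0 rose and 1 fell of 20, camera adjusted p = 0.0529) was called lower under 7 alternatives. They were RLE factors (adjusted p = 0.0297), no filter (0.0121), the replicate block (0.0480), the GC trend removed (0.0353), only the 6 libraries (0.0136), converted replicate 2 left out (0.0448) and cR replicate 2 left out (0.0413; range 0.0121 to 0.693). The hypoblast list (camera adjusted p = 0.0565) was called lower with the GC trend removed (adjusted p = 0.0357), on only the 6 libraries (adjusted p = 0.0140) and by fry (adjusted p = 0.0485; range 0.0140 to 0.398). On only the 6 libraries 4 more lists were called lower: core pluripotency (adjusted p = 0.00785, range 0.00785 to 0.393), naive pluripotency (adjusted p = 0.000734, range 0.000734 to 0.681), eight-cell-like (adjusted p = 0.0229, range 0.0229 to 0.522) and NODAL/TGF-beta targets (adjusted p = 0.000734, range 0.000734 to 0.752). Median, mean and test differed in sign in the fibroblast list and in 10 uncalled ones: trophectoderm and trophoblast, amnion, primitive streak and mesoderm, neuroectoderm, FGF/ERK, oxidative phosphorylation, cholesterol, amino acid stress, mesenchymal and matrix, and apoptosis.

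By edgeR, 597 of 20908 genes differed, 330 higher and 267 lower in converted, 53 of them at least 2-fold (33 higher, 20 lower), and 3397 had an unadjusted p under 0.05. The split was 278 higher and 276 lower with RLE factors. Adjusted p-values of the 14 named genes that passed in edgeR were 2.21e-09 to 0.0256, with no overlap between groups. Their log2 SE were 0.05 to 0.26 where both groups had over 3 counts. The count changed with single libraries left out: it was 261 (145 higher, 116 lower; 33 at least 2-fold) without converted replicate 1, 173 (86 higher, 87 lower; 17) without converted replicate 3, 395 (233 higher, 162 lower) without cR replicate 1, 201 (95 higher, 106 lower; 25) without cR replicate 2 and 228 (117 higher, 111 lower; 31) without cR replicate 3, and 1711 (874 higher, 837 lower) on only the 6 libraries compared. The 95% interval of the difference lay within 2-fold either way for 16123 of 20908 genes (77.1%), for 25 of the 27 naive markers and for 19 of the 25 primed markers.

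Converted against coculture compares the later with the earlier step of the coculture route. Naive markers were all higher in converted: all 27 measured rose (median log2 change 11.61, 9.50 with zero genes at their bound, camera adjusted p = 7.20e-16). NLRP7 rose at least 76454-fold, from 0 to 5049.5 ± 111.99 CPM. DPPA5 rose at least 6678-fold, from 0 to 441 ± 20.8 CPM. NANOG rose 97.7-fold, from 3.35 ± 1.08 to 324 ± 10.3 CPM (log2 fold change 6.61 ± 0.27 (SE), edgeR adjusted p = 3.43e-27). TDGF1 rose 266-fold, from 1.42 ± 0.658 to 394 ± 16.04 CPM, and in the core list of 13 measured members 9 rose and 4 fell (median log2 change 2.41, camera adjusted p = 0.0295, but adjusted p = 0.0982 with an estimated correlation). All 20 measured eight-cell-like genes rose (median 7.30, 5.34 with zero genes at their bound, camera adjusted p = 2.23e-07). TRIM43B rose at least 126-fold, from 0 to 8.33 ± 0.719 CPM. For primed markers, 3 of 25 rose, 19 fell and 3 did not pass (median log2 change -3.72, camera adjusted p = 1.55e-05). SOX11 fell 1001-fold, from 344 ± 4.71 to 0.339 ± 0.156 CPM.

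Of the lists called higher in coculture than in primed, hypoxia, glycolysis, cholesterol, fibroblast, neuroectoderm and imprinted genes were called lower in converted than in coculture. All 15 hypoxia targets fell (median log2 change -2.26, camera adjusted p = 5.49e-06, but 0.0982 with an estimated correlation). NDRG1 fell 51.3-fold, from 319 ± 16.9 to 6.24 ± 1.83 CPM. For glycolysis, 1 of 20 rose and 19 fell (median log2 change -1.46, camera adjusted p = 2.16e-07, but 0.152 with an estimated correlation). SLC2A1 fell 5.97-fold, from 1489 ± 60.8 to 249 ± 78.4 CPM. For cholesterol synthesis, 2 of 20 rose and 18 fell (median log2 change -1.21, camera adjusted p = 1.78e-05, but 0.204 with an estimated correlation). HMGCS1 fell 5.41-fold, from 1572 ± 479.8 to 290.4 ± 17.96 CPM. All 11 fibroblast genes fell (median log2 change -4.81, camera adjusted p = 2.13e-05). COL1A2 fell 245-fold, from 556 ± 16.3 to 2.27 ± 0.481 CPM. For neuroectoderm, 9 of 11 measured fell and 2 did not pass (median log2 change -3.46, camera adjusted p = 0.000513). MAP2 fell at least 2782-fold, from 233 ± 35.2 to 0 CPM. For imprinted genes, of 21 measured members 4 rose, 15 fell and 2 did not pass (median log2 change -1.02, camera adjusted p = 0.0227, but adjusted p = 0.204 with an estimated correlation). DLK1 fell 162-fold to 5.14 ± 0.435 CPM and NNAT 27.9-fold to 8.14 ± 0.929 CPM. MEG3 rose 127-fold to 1451 ± 86.3 CPM and PEG3 at least 829-fold, from 0 to 54.7 ± 2.83 CPM. YAP/TEAD targets were lower, and of 15 measured members 3 rose, 11 fell and 1 did not pass (median log2 change -1.72, camera adjusted p = 0.00492, but adjusted p = 0.118 with an estimated correlation). AXL fell 323-fold, from 83.9 ± 4.75 to 0.253 ± 0.0934 CPM.

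Other called lists were higher in converted. All 13 mitochondrially encoded mRNAs rose (median log2 change 1.40, camera adjusted p = 3.41e-05, but 0.183 with an estimated correlation). MT-CO2 rose 4.16-fold, from 906 ± 99.8 to 3765 ± 306 CPM, while the call of MT-ATP8 (1.03 ± 0.837 against 0.223 ± 0.156 CPM) ended without converted replicate 2 (edgeR adjusted p = 0.149; range 0.00106 to 0.149). For oxidative phosphorylation, 27 of 28 rose and 1 did not pass (median log2 change 1.12, camera adjusted p = 4.54e-09). NDUFV1 rose 4.68-fold, from 96.4 ± 3.40 to 451 ± 22.6 CPM. For proliferation, 18 of 20 rose and 2 fell (median log2 change 0.998, camera adjusted p = 3.41e-05, but 0.201 with an estimated correlation). CCNE1 rose 7.41-fold, from 10.9 ± 1.74 to 80.7 ± 2.17 CPM. For epithelial adhesion, 13 of 16 rose and 3 fell (median log2 change 1.17, camera adjusted p = 0.000952). ESRP1 rose 94.6-fold, from 2.10 ± 0.508 to 197 ± 5.27 CPM. For germ cell genes, of 9 measured members 7 rose, 1 fell and 1 did not pass (median log2 change 4.58, camera adjusted p = 0.01196, but adjusted p = 0.0793 with an estimated correlation). MAEL rose 31.6-fold, from 0.523 ± 0.173 to 16.3 ± 1.502 CPM. DAZL, an RNA-binding protein of germ cells, fell from 8.99 ± 2.34 to 0.0851 ± 0.0837 CPM, a count ratio of 108 (95% interval 36.6 to 525). For DNA methylation enzymes, of 12 measured members 8 rose, 2 fell and 2 did not pass (median log2 change 0.76, camera adjusted p = 0.0227, but adjusted p = 0.0982 with an estimated correlation). ZFP57 rose at least 1008-fold, from 0 to 66.4 ± 4.79 CPM. DNMT3B rose 2.39-fold, from 229 ± 6.71 to 549 ± 7.25 CPM. For apoptosis, of 17 measured members 10 rose, 3 fell and 4 did not pass (median log2 change 0.55, camera adjusted p = 0.0455, but adjusted p = 0.135 with an estimated correlation). CASP8 rose 61.0-fold, from 0.7999 ± 0.103 to 48.8 ± 3.49 CPM. This last call also ended with the replicate block (adjusted p = 0.0559), with the GC trend removed (adjusted p = 0.0534) and on only the 6 libraries compared (adjusted p = 0.0593; range 6.99e-10 to 0.135).

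Camera left 14 lists uncalled, among them trophectoderm and trophoblast (3 rose and 5 fell of 9, adjusted p = 0.733), amnion (3 rose and 2 fell of 7, adjusted p = 0.733) and hypoblast (3 rose and 6 fell of 11, adjusted p = 0.262). Also uncalled by camera were primitive streak and mesoderm (2 rose and 3 fell of 7, adjusted p = 0.846) and mouse ESC genes (5 rose and 5 fell of 11, adjusted p = 0.926). Signalling lists uncalled by camera were FGF/ERK targets (5 rose and 12 fell of 21, adjusted p = 0.129), NODAL/TGF-beta targets (8 rose and 6 fell of 15, adjusted p = 0.238) and WNT targets (4 rose and 10 fell of 14, adjusted p = 0.0641). Nor did camera call JAK/STAT3 targets (10 rose and 2 fell of 14, adjusted p = 0.0811) and p53 targets (8 rose and 12 fell of 22, adjusted p = 0.325). Camera also left uncalled NF-kB targets (5 rose and 2 fell of 9, adjusted p = 0.0906) and interferon response (6 rose and 5 fell of 12, adjusted p = 0.723). The last, by camera, were amino acid stress response (9 rose and 5 fell of 17, adjusted p = 0.215) and mesenchymal and matrix (4 rose and 10 fell of 15, adjusted p = 0.0906). Without a filter camera called JAK/STAT3 and NF-kB higher and WNT and mesenchymal and matrix lower (adjusted p from 0.0122 to 0.0392; range over these lists and all alternatives 7.55e-11 to 0.244). FZD7 fell 591-fold, from 252 ± 17.2 to 0.422 ± 0.314 CPM. NODAL rose 98.8-fold, from 1.98 ± 0.490 to 195 ± 6.34 CPM. By edgeR, 16234 genes changed, 8009 higher and 8225 lower, and 9908 at least 2-fold (4631 higher, 5277 lower). The split was 7593 higher and 8625 lower with total-count scaling, and 7356 higher and 8934 lower with the GC trend removed. Adjusted p-values of the 129 named genes that passed in edgeR were 4.31e-33 to 0.00602, with no overlap between groups. Their log2 SE were 0.03 to 0.73 where both groups had over 3 counts. Camera called 18 of 32 lists, and 7 with an estimated correlation. Adjusted over the list alone, the counts were the same in all 32 lists, and median, mean and test differed in sign in 4 uncalled lists: trophectoderm and trophoblast, amnion, hypoblast and mouse ESC genes.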

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

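The GC correction was not planned. With a correlation estimated per list, camera called 5 lists in cR against primed, 0 in converted against cR and 7 in converted against coculture. By fry 28 lists were called in converted and 28 in cR against primed, and 30 in converted against coculture. Without a filter camera called 15 in converted against primed. Fry also turned the list trophectoderm and trophoblast, lower but uncalled by camera, to higher in cR against primed (median log2 fold change -0.31, mean 0.97) and in converted against coculture (median -1.57, mean 1.15), and the cause was not tested. On only the 6 libraries compared, 1711 genes and 12 lists differed between converted and cR. The coefficient of variation was 7.70% over all 12 libraries but 5.40% in converted and 5.06% in cR. So the single fit may call too few genes here, which was not tested. Leaving out a library gave 173 to 410 genes, 17 to 44 of them at least 2-fold, from causes not tested. The correlation of converted and cR changes was 0.8796 without a filter, 0.992 for genes of at least 10 CPM and 0.968 to 0.973 with a library left out, and that of coculture and cR changes 0.283 and 0.0948 in the same order without a filter and at 10 CPM, from causes not tested. With replicate number as a block, without evidence of pairing, 13203, 15662, 15726, 600 and 16133 genes changed in the comparisons of coculture, converted and cR with primed, converted with cR and converted with coculture, and 18, 9, 9, 7 and 17 lists were called. The GC correction moved the median log2 fold change of all genes to -0.14 in converted and in cR against primed and -0.15 in converted against coculture. Over all alternatives, results for single lists kept direction and call in 2269 cases, lost the call in 33, gained it in 86 and turned in 2, and those for named genes kept both in 7552, lost the call in 15 and gained it in 1. Other counts of genes stayed within 1.5 times the reported ones. The share of mouse counts was not run. Depth limits genes near 3 counts per group, where folds are bounds or carry counting intervals.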

Other observations

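Gene families were chosen after the data were seen, and camera's adjusted p-values here use an estimated correlation. Of 11 body-axis (HOX) genes past the filter, 10 rose in converted (median log2 fold change 7.29, camera adjusted p = 0.0198). In cR 10 rose (7.46, adjusted p = 0.0199), and in coculture 5 (adjusted p = 0.101). Genes at 0 in primed pass the filter only if another group expresses them, which favours rises. Metallothioneins, which bind zinc and copper, fell in coculture in 6 of 8 cases (median -3.40, camera adjusted p = 0.0249), and all 8 rose in converted (3.66, adjusted p = 0.00935) and in cR (4.10, adjusted p = 0.00785). In converted 5 of these 8 were lower than in cR (median -0.38, camera adjusted p = 0.0298). Of 39 collagen genes 29 fell in converted (median -2.51, camera adjusted p = 0.00537) and 29 in cR (-2.19, adjusted p = 0.00733). Of 80 ribosomal protein genes 72 rose in coculture (median 0.71, camera adjusted p = 0.101), 73 in converted (0.44, adjusted p = 0.127) and 73 in cR (0.41, adjusted p = 0.149). In cR 241 of 493 zinc finger (ZNF) genes rose and 125 fell (camera adjusted p = 0.152), and 38 of 59 protocadherins fell (adjusted p = 0.0993).

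The test on mouse orthologues, the whole-difference tests of GC content and depth and the GC correction were chosen after seeing the results. The real grouping was set beside other groupings of the same libraries. In each of the 5 comparisons 1 of 10 splits of the 6 libraries, the real one, gave as many genes: 12640 for coculture and 15888 for converted and 15991 for cR against primed, 1711 for converted against cR and 14881 for converted against coculture, each with 0 in the highest other split. With 10 splits no share can fall under 0.1.

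Genes that rose in coculture might hold reads of mouse ESC RNA. A trend on GC content as the cause is argued against, since 94.8% of the genes that rose at least 2-fold remained with it removed. Orthologues of genes abundant in mouse ESCs and under 10 CPM in primed had a median log2 fold change of -1.31. Of 10, 3 were higher and 7 lower (exact sign test p = 0.344), and 1 rose and 5 fell. All 17 (median -2.41, 3 higher and 14 lower) cannot decide, as genes abundant in primed, like POU5F1, fell. Strongly conserved genes had a median of -0.057 (10 higher and 20 lower of 30, exact sign test p = 0.0987). Members moved both ways and the table holds no mouse genes, so mouse RNA on part of the genes that rose stays open. So does a response of human cells to mouse cells or other coculture conditions. No test here separates these.

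The 597 genes that differ between converted and cR might reflect GC content or depth. As the whole difference both are argued against: 493 calls (82.6%) remained with the GC trend removed and 520 (87.1%) with all libraries thinned to the smallest total. For the calls that ended, a part from either stays open, as does a biological difference between the routes. Shared handling of the 3 libraries of a group is confounded with the group.

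The higher COL1A1, COL1A2 and COL3A1 in cR than in converted may come from fibroblast RNA in the cR libraries. A GC trend is argued against, since at least 98.7% of each log2 fold change was left with it removed. Of a second list of 25 fibroblast genes, 9 could be used and 5 of them were higher in cR (exact sign test p = 1), with 30 counts in converted and 29 in cR, while LUM held 0 and 17 counts and DCN 1 and 12. SPARC, which both states express, was at 569.7 and 579.6 CPM in converted and cR. VIM, abundant in fibroblasts, held 18 counts in converted and 10 in cR. COL6A1, COL6A2 and BGN, which both groups express, held 4638, 1892 and 41 in converted and 3458, 1445 and 21 in cR. FBLN1, FBLN2, MFAP5, LOXL1 and CTSK were lower in cR too. SERPINF1 (2166 and 2667), FSTL1 (501 and 558), COL5A2 (38 and 65), CCDC80 and TWIST2 were higher. These values point different ways, so fibroblast RNA and expression by the cR cells themselves both stay open.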
